A study of Mus musculus with 3 samples.

How the data were processed

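Single-cell expression was measured in 3 whole-skin libraries, 1 per group (control, UV, UV plus vitamin D), grouped by the treatment in the labels. The deposited values are whole-number counts per gene and cell barcode, 1 table per library. Per the submitters' processing notes the tools were FastQC, fastp, STAR and featureCounts, with no versions and the build GRCh38, a human build. The gene symbols are mouse symbols: 98.1%, 98.0% and 98.1% of those in the control, UV and UV plus vitamin D tables were found in the mouse GENCODE annotation used here. The build the authors aligned to is therefore left open, no coordinates are given, and genes are named by the symbols in the deposited tables. Whether the deposited counts are unique molecules or reads is not given in the sources used here; they were treated as counts of molecules, and if reads were counted the intervals are too narrow. The tables list 22129, 23944 and 21814 genes, 26989 in any of them, and the lowest barcode total was 2822, 3010 and 3409, so barcodes had been selected before deposit, with a different lowest total in each library.

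The tables held 9098, 5502 and 6234 barcodes. Barcodes with fewer than 200 detected genes (17, 35 and 34) and those with more than 20% of counts from mitochondrially encoded genes (3, 16 and 1) were left out. Scrublet called 0, 1 and 0 doublets; a caller that marks under 0.5% of cells has not worked, so doublets remain among the cells. Removing the 5% of cells with the highest Scrublet scores, or the cells with at least 1% of counts from markers of an unrelated lineage (13, 90 and 20 cells), served as alternatives chosen after seeing the data. Total counts were 79450666, 50601456 and 69126823 in the cells kept. The median mitochondrial percentage was 2.90%, 2.74% and 2.15%, the rRNA gene took 11.4%, 10.4% and 7.22% of counts, and haemoglobin genes 0.0808%, 0.131% and 0.193%. All libraries had the expression pattern of male animals: Xist had 1, 0 and 0 counts, and Ddx3y was at 86.9, 70.2 and 80.6 CPM.

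Cells of the 3 libraries were clustered together after log normalisation to 10000 counts per cell, with 2000 variable genes chosen within library, 30 principal components, 15 neighbours and Leiden resolution 1, with no correction between libraries. Clusters were named from fixed marker lists of 21 cell types. A name needed at least 3 of its markers detected in 25% of the cluster's cells, and either a marker among its top 10 genes or at least 6 such markers. The second way of meeting this was added after the data were seen, because keratinocyte clusters lost their names under other cell filters. Cluster 22 stayed unnamed and held 0.220%, 3.30% and 0.290% of cells. The Langerhans cell cluster, number 23 (58, 43 and 23 cells), had more markers of another class among its leading genes and is not compared under that name, although its cells count as immune. No endothelial class was found at these settings, although a cluster met the markers of blood endothelial cells with library means subtracted before clustering, so the angiogenesis and endothelial activation list was not compared.

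Counts were summed per library and class and given as CPM, counts scaled to a common class total, computed here and not by the authors. Log2 ratios are of CPM plus a pseudocount of 10, which shrinks the ratios of low genes; folds are ratios of CPM without it, with exact conditional intervals. A gene with 0 counts in a library was set against a floor of 3 counts. The exact conditional interval of such a gene starts below that bound: at 121.567-fold and 83.67-fold for Ly6c2 in the UV against control and UV plus vitamin D against UV comparisons, 51.7-fold for Ifng, 19.46-fold for Gzma and 14.59-fold for Wfdc12. Shares of cells have exact binomial intervals, and ratios of shares have counting intervals on the log scale. Gene values were compared in classes with at least 50 cells in each library; shares were also compared for smaller classes, such as sebocytes with 33 cells in the UV plus vitamin D library. For each of 22 gene lists, fixed with a lead class before the data were examined, the median log2 ratio over members with at least 20 counts is given with its order-statistic interval, the members at least 1.5-fold apart on that log2 scale with the pseudocount, and the percentile among 10000 random lists matched on expression, as a description of these libraries.

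Named genes followed a rule fixed before the data were examined. In keratinocytes, fibroblasts, and macrophages with monocytes and dendritic cells, these were the 5 highest and 5 lowest log2 ratios among genes with at least 50 counts in the higher library, a CPM of at least 0.2 of that in the highest class, and an interval wholly beyond 1.5-fold. Mitochondrial, ribosomal protein and haemoglobin genes and unnamed models were excluded. Up to 4 members of each list in its lead class were added, and Vdr, Cyp24a1 and Cdkn1a in keratinocytes whatever their values. The share of a gene's counts from 1 cell was computed for each. The groups, classes, lists, comparisons and the alternatives not marked otherwise were also fixed before the data were examined.

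The relation between the 2 ratios across genes used UV cells split at random into separate sets, with genes of at least 50 counts, and 20 Poisson simulations with no difference. A single split was planned; the mean over 20 splits replaced it after the value was seen to vary with the split. Scaling by the median of gene ratios was also compared with class totals. The log2 ratio of its scale factors, minus that of the totals, is given here. For UV plus vitamin D against UV it was -0.11 in all cells, 0.14 in immune cells and 0.23 in T and NK cells. For UV against control it was -0.13 in suprabasal keratinocytes and -0.11 in T and NK cells. All log2 ratios of genes move by the same amounts with the opposite sign.

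The ratio step was tested on simulated counts with 200 changed genes per comparison. All genes changed 4-fold were named as beyond 1.5-fold in each of the 6 comparisons. Of genes changed 2-fold, 89% were recovered in keratinocytes for UV against control (9823 genes), 68% in fibroblasts (2344 genes) and 77% in macrophages, monocytes and dendritic cells (1813 genes); for UV plus vitamin D against UV these were 91% (9764 genes), 70% (2572 genes) and 74% (1292 genes). Unchanged genes were named in 0% of cases. The simulated counts were Poisson draws with no spread between cells or libraries, so these percentages cover counting error only. In the data the same rule also named genes with nearly all counts from 1 cell, such as Igkc in keratinocytes. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.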

Results

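Whole skin of 9-week-old C57BL/6 mice was dissociated and sequenced as single cells with the Singleron GEXSCOPE kit, which tags each captured transcript with a cell barcode. The series has 3 libraries, 1 for each of 3 groups: unirradiated skin with saline (control), irradiated skin with saline (UV), and irradiated skin with the treatment labelled VD, read here as the vitamin D of the series title (UV plus vitamin D). The title names UVB, inflammation linked to photoaging, and protection by vitamin D as the questions. After filtering, 9078 control, 5450 UV and 6199 UV plus vitamin D cells remained, with 79450666, 50601456 and 69126823 counts. The median cell held 6822.5, 7565.5 and 9301 counts and 1703.5, 1814.5 and 2043 genes. There are no replicates, so no difference was tested across samples, and each comparison describes these libraries, not the conditions. Intervals in square brackets are 95% intervals; those of shares, ratios and gene folds cover counting error only, and those of list medians cover the spread over list members. List medians, and counts of list members at least 1.5-fold apart, use log2 ratios with a pseudocount of 10 CPM, which shrinks low genes; counts by CPM without it are given where they differ much.

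The UV against control comparison asks how irradiated skin differed from unirradiated skin. Keratinocytes, the cells that build the epidermis, made up 93.3% [92.8, 93.9] of control cells and 65.9% [64.7, 67.2] of UV cells, a share 1.42-fold lower [1.39, 1.44]. Immune cells made up 3.54% [3.17, 3.94] and 14.7% [13.8, 15.7], which is 4.16-fold higher [3.67, 4.72]. Macrophages, monocytes and dendritic cells were 1.48% and 10.8% of cells, 7.32-fold higher [6.09, 8.81], and T and NK cells 1.42% and 3.12%, 2.20-fold higher [1.75, 2.75]. Fibroblasts, which make the dermal matrix, were 2.20% and 6.92%, 3.14-fold higher [2.65, 3.71], and sebocytes, the lipid-producing cells of the sebaceous gland, 0.639% and 2.40%, 3.76-fold higher [2.77, 5.12].

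Within the keratinocytes, basal cells were 17.9% of control cells and 8.79% of UV cells, suprabasal cells 69.2% and 45.7%, and hair follicle keratinocytes 6.23% and 11.4%. Hair matrix and shaft cells, which form the growing hair, numbered 313 in UV (5.74% [5.14, 6.39]), and melanocytes, the pigment cells, numbered 48 (0.881% [0.650, 1.17]). Neither was found among the 9078 control cells, which allows a share of up to 0.0330% at a limit of 3 cells and 0.0406% by the exact interval. Both clusters came from the UV library alone, so each may be a trait of that library. A cluster left without a name held 20 control cells (0.22%) and 180 UV cells (3.30%). No cluster met the markers of endothelial cells at these settings. With library means subtracted before clustering, a cluster met those of blood endothelial cells, so such cells may be present. When each cell was assigned on its own from its markers, the log2 ratio of the T and NK cell share was 2.50, against 1.13 from clusters, and that of the immune share 2.67, against 2.06.

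**Figure D1:**
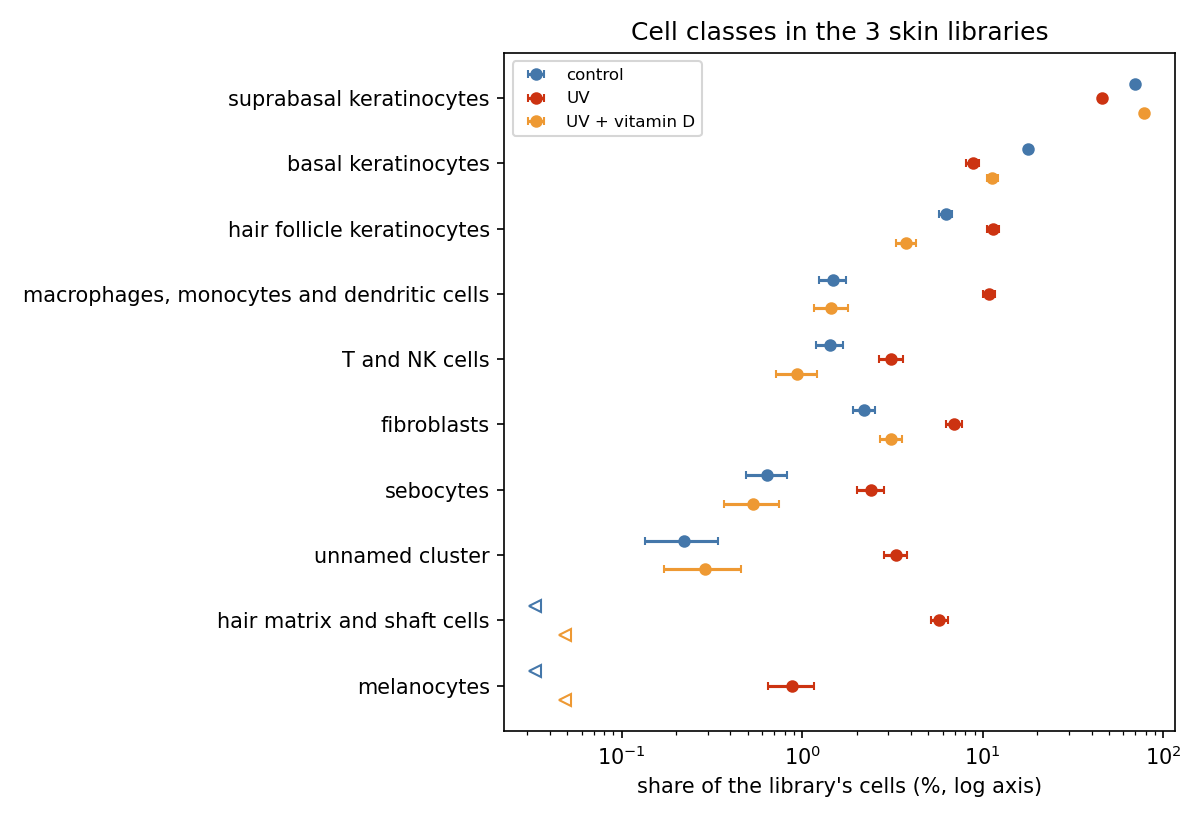
Share of each library's cells (percent, log axis) in 10 classes, with exact 95% binomial intervals as bars; open triangles mark 0 cells, drawn at the share that 3 cells would give. The UV library holds 10.8% macrophages, monocytes and dendritic cells, against 1.48% in control and 1.45% in UV plus vitamin D.

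In keratinocytes, genes of the stressed epidermis stood higher in UV. Of 22 measured members of the epidermal stress and alarmin list, 11 were at least 1.5-fold higher and 0 lower (14 and 0 by CPM without the pseudocount), with a median log2 ratio of 0.67 [0.41, 2.07] (percentile 100 among 10000 matched random lists), or 1.5 with a pseudocount of 1 CPM. Krt6a, a keratin of wound-edge and follicle epidermis, was at 23.3 CPM (counts scaled to a common class total) in control and 237 in UV, 10.2-fold higher [9.68, 10.7]. Krt6a and Krt17 of this list are also markers used to name hair follicle keratinocytes. These were 566 of 8474 keratinocytes in control and 623 of 3593 in UV, so the mix of classes may enter the ratios of both genes. Krt6b had 1 count in control and 5568 in UV, or 0.0132 and 145 CPM. Sprr1b, a cornified envelope precursor, was 8.09-fold higher [7.99, 8.19], and the cystatin family genes Stfa1 and Stfa3 were 15.4-fold [14.4, 16.4] and 55.9-fold [50.8, 61.6] higher. Differentiation and barrier genes were also higher, with 12 of 34 at least 1.5-fold up, 0 down and a median of 0.41 [0.23, 0.70] (percentile 100). Among them Rptn (repetin) was 60.8-fold higher [51.2, 72.8], Flg (filaggrin) 9.76-fold [9.51, 10.02] and Hrnr (hornerin) 3.46-fold [3.40, 3.53].

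Other keratinocyte genes stood lower in UV. Igfbp3, which binds insulin-like growth factors, went from 421 to 95.9 CPM, 4.38-fold lower [4.24, 4.54]. Nr1d1, a repressor of the circadian clock, was 3.0-fold lower [2.76, 3.26], Ifi202b 2.56-fold [2.52, 2.60], the cytokine gene Il33 2.34-fold [2.25, 2.44] and Nfkbia, the inhibitor of NF-kB, 2.21-fold [2.19, 2.24]. Of 17 genes of basal keratinocyte adhesion, 4 were at least 1.5-fold lower and 0 higher, with a median of -0.16 [-0.52, 0.03] (percentile 7.37), or -0.04 with basal, suprabasal and follicle cells weighted as in control; Dst (dystonin) was 2.47-fold lower and Col17a1, the collagen of hemidesmosomes, 1.89-fold. Of 27 p53 and DNA damage genes, 3 were lower and 0 higher (6 and 3 by CPM without the pseudocount), with a median of -0.07 [-0.25, 0.05]; Cdkn1a, which encodes the cell cycle inhibitor p21, was at 2487 CPM in control and 1644 in UV, 1.51-fold lower [1.5, 1.53]. Cluster 0 held the most keratinocytes in control (2107 cells) and cluster 8 in UV (749 cells). The immunoglobulin genes Igkc and Ighm also met the naming rule, but 98.7% and 98.1% of their UV counts came from 1 cell, and without cells that carry markers of an unrelated lineage their log2 ratios were 1.13 and 0.38, against 6.59 and 4.10.

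Of 21 genes of the vitamin D receptor and its targets in keratinocytes, 4 were at least 1.5-fold higher and 2 lower in UV (8 and 4 by CPM without the pseudocount), with a median of 0.13 [-0.04, 0.25]. The receptor gene Vdr was at 66.5 CPM in control and 47.8 in UV, 1.39-fold lower [1.32, 1.47]. Cyp24a1, the enzyme that inactivates vitamin D, had 0 counts in control and 5 in UV, too few for a fold. The cell cycle list had a median of 0.12 [0.05, 0.29], with 3 of 35 members at least 1.5-fold higher and 0 lower, or 20 higher and 2 lower by CPM without the pseudocount; Top2a, a topoisomerase of dividing cells, was at 3.99 and 12.7 CPM. The medians were 0.15 [-0.11, 0.30] for hypoxia and glycolysis, 0.01 [-0.08, 0.09] for antioxidant and metallothionein genes and 0.04 [-0.11, 0.14] for nuclear-encoded oxidative phosphorylation.

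In fibroblasts, matrix genes stood higher in UV. Of 44 measured genes of fibrillar collagen and dermal matrix, 21 were at least 1.5-fold higher and 0 lower, with a median of 0.55 [0.46, 0.68] (percentile 100). Lum, the collagen-binding proteoglycan lumican, was at 931 and 2668 CPM, 2.87-fold higher [2.68, 3.06], and Eln (elastin) 3.29-fold higher [2.39, 4.63]. Of 24 matrix proteases and inhibitors, 7 were higher and 1 lower, with a median of 0.38 [0.13, 0.61]; the inhibitor Timp1 was 4.87-fold higher [3.56, 6.82] and the stromelysin gene Mmp3 2.44-fold [2.18, 2.75]. Of 27 genes of senescence-associated secretion, 9 were higher and 1 lower, with a median of 0.06 [-0.26, 0.75]; the chemokine gene Ccl8 was 5.63-fold higher [4.36, 7.37]. The naming rule, which ranks log2 ratios with the pseudocount, also named the neutrophil-attracting chemokine gene Cxcl5 (20.3-fold [11.3, 40.9]), the interferon-induced genes Ifit3 (48.1-fold [13.2, 399]) and Ifit1 (12.7-fold [7.84, 21.9]), Prg4 and Cilp as higher.

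Sult1e1, an oestrogen sulfotransferase, was 16.3-fold lower [12, 22.7] in UV fibroblasts, and Hmox1, which encodes haem oxygenase 1, 5.79-fold lower [5.39, 6.22], from 2431 to 420 CPM. Sfn was 3.45-fold lower [3.15, 3.78], from 1064 to 308 CPM, and stood at 4589 and 3996 CPM in keratinocytes. Krt5, a keratin of basal keratinocytes chosen after its values were seen, was at 233 and 83.4 CPM in these fibroblasts. Cluster 12 held most fibroblasts in control (148 of 200 cells) and cluster 19 most in UV (194 of 377). Col1a1, Col1a2, Col3a1 and Lum of the matrix list are among the leading genes of cluster 19. The matrix ratios may therefore also reflect the mix of fibroblast clusters. Within single clusters the log2 ratios of several genes differed: Lum was 0.71 in cluster 19 against 1.51, Mmp3 0.45 in cluster 19 against 1.26, Eln 0.74 in cluster 12 against 1.5, Timp1 1.20 in cluster 19 and 2.62 in cluster 12 against 2.03, Hmox1 -1.46 in cluster 19 against -2.51, Cilp 0.12 in cluster 12 against 2.89, and Ifit3 1.24 in cluster 19 against 3.05. In cluster 19, Ifit1 was 2.19 against 3.02, Prg4 2.02 against 2.89 and Sult1e1 -2.70 against -3.45. Without cells of the highest doublet scores, Cxcl5 was 4.28 against 3.42 and Ccl8 2.92 against 2.31. Ereg and Slpi also met the rule as lower, but 79.4% and 93.7% of their control counts came from 1 cell, they stood at 310 and 102 CPM in control keratinocytes, and their direction turned in cluster 19 (0.20 and 0.44).

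In macrophages, monocytes and dendritic cells, named genes stood apart in both directions. Ly6c2, a surface marker of inflammatory monocytes, had 0 counts in control and 1965 in UV, at least 149.6-fold higher. Ms4a4c was 29.9-fold higher [17.4, 56.2], and Spp1, which encodes the secreted protein osteopontin, 31.1-fold [13.2, 96.0]. Ifnb1, which encodes interferon beta, was at 491 and 18.3 CPM, 26.9-fold lower [20.4, 36.0], and the interferon-induced genes Ifit1, Rsad2 and Cmpk2 were 10.4-fold [9.25, 11.7], 7.15-fold [6.72, 7.61] and 6.48-fold [5.16, 8.17] lower. The interferon response list went both ways in this class, with 19 of 40 members at least 1.5-fold higher, 11 lower and a median of 0.56 [0.01, 0.90]. Cluster 11, with markers of dendritic cells and macrophages, held 459 of the 589 UV cells of this class, and cluster 16 held 114 of the 134 control cells. In cluster 16 alone the log2 ratios were smaller, at 0.85 for Ly6c2 against 5.95, 1.55 for Ms4a4c against 4.28, 1.44 for Spp1 against 3.72, -3.34 for Ifnb1 against -4.15, -2.39 for Ifit1 against -3.28, -1.76 for Rsad2 against -2.81 and -1.48 for Cmpk2 against -2.43.

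The list of class II antigen presentation had 7 of 15 members at least 1.5-fold higher in UV and 1 lower in this class, with a median of 0.58 [0.15, 1.14] (percentile 99.9); in cluster 16 alone the median was -0.28. Ctss, a protease that trims the class II invariant chain, was 3.62-fold higher [3.37, 3.89]; its log2 ratio was 0.76 in cluster 16 against 1.85. The classically activated macrophage list went both ways, with 5 of 16 higher, 6 lower and a median of 0.01 [-0.87, 0.83], or -0.59 over members with at least 100 counts. Il1b, which encodes interleukin 1 beta, was 2.93-fold higher [2.62, 3.29], and Il6 was 3.21-fold lower [2.54, 4.04]. Of 23 genes of alternative activation, 11 were lower and 6 higher, with a median of -0.41 [-0.77, 0.58] (percentile 0); Retnla, a marker of that state, was at 14910 and 4242 CPM, 3.51-fold lower [3.43, 3.60], and Trem2, a lipid receptor of macrophages, was 5.73-fold higher [3.81, 9.01]. In cluster 16 alone, the median of the alternative activation list turned to 0.42, and the log2 ratio of Il1b was 2.82 against 1.53, of Il6 -0.40 against -1.52, of Trem2 1.48 against 2.21 and of Retnla -0.56 against -1.81.

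In T and NK cells, genes of T-cell subsets and effectors stood higher in UV. Of 30 measured genes of this list, 21 were at least 1.5-fold higher and 5 lower, with a median of 1.59 [0.96, 2.04] (percentile 100). Ifng, which encodes interferon gamma, had 0 counts in control and 193 in UV, at least 64.2-fold higher, and the granzyme gene Gzmc was at 4.06 and 1229 CPM, 302-fold higher [118, 1111]. The granzyme gene Gzmb had 2 counts in control and 166 in UV, a ratio of 82.8 [22.6, 690]. Other settings gave larger log2 ratios, at 5.09 for Ifng with each cell assigned on its own against 4.36, and 7.06 for Gzmc without cells of the highest doublet scores against 6.46.

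Summed over all cells, 22 of 40 inflammatory mediators were at least 1.5-fold higher in UV and 4 lower (29 and 5 by CPM without the pseudocount), with a median of 0.89 [0.41, 1.08] (percentile 100). Vcam1, an adhesion molecule for leukocytes, was 14.9-fold higher [13.2, 16.8], Il1b 7.33-fold [6.86, 7.84] and the monocyte-attracting chemokine gene Ccl7 4.31-fold [4.24, 4.37]; with each cell weighted the same, the log2 ratio of Il1b was 2.94 against 2.21. With each class weighted to its share in control, the median of the mediators was -0.01; within keratinocytes it was 0.19, within fibroblasts 0.23 and within macrophages, monocytes and dendritic cells -0.36. Of 40 interferon response genes, 18 were higher and 0 lower (32 and 1 by CPM without the pseudocount), with a median of 0.56 [0.39, 0.80] (percentile 100), or 1.54 with a pseudocount of 1 CPM; Bst2, which tethers virus particles, was 10.7-fold higher [9.65, 11.8]. The interferon median was 0.21 with classes weighted to control shares, 0.21 [0.06, 0.27] within keratinocytes, 0.79 [0.64, 0.97] within fibroblasts and 1.29 [0.92, 1.75] within T and NK cells.

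Hair follicle growth genes had a median of 0.61 [0.25, 2.09], or 2.03 with a pseudocount of 1 CPM, with 12 of 23 higher and 1 lower (19 and 2 by CPM without it). Krt71, an inner root sheath keratin, had 0 counts in control and 7262 in UV. The list's median was 0.05 with classes weighted to control shares. That weighting leaves out the hair matrix and shaft cells, since control held 0 of them, so a fall of the median follows from the weighting itself. Sebaceous and lipid synthesis genes had a median of 0.23 [0.02, 0.55], with 7 of 25 higher and 1 lower (13 and 1 by CPM without the pseudocount); Soat1, which esterifies cholesterol, was 7.95-fold higher [7.20, 8.79]. The immediate early and heat shock list had a median of 0.14 [0.02, 0.37], or 0.0088 with classes weighted to control shares, with 7 of 36 higher and 1 lower. Socs3, a feedback inhibitor of cytokine signalling, was 3.20-fold higher [2.95, 3.48].

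**Figure D2:**
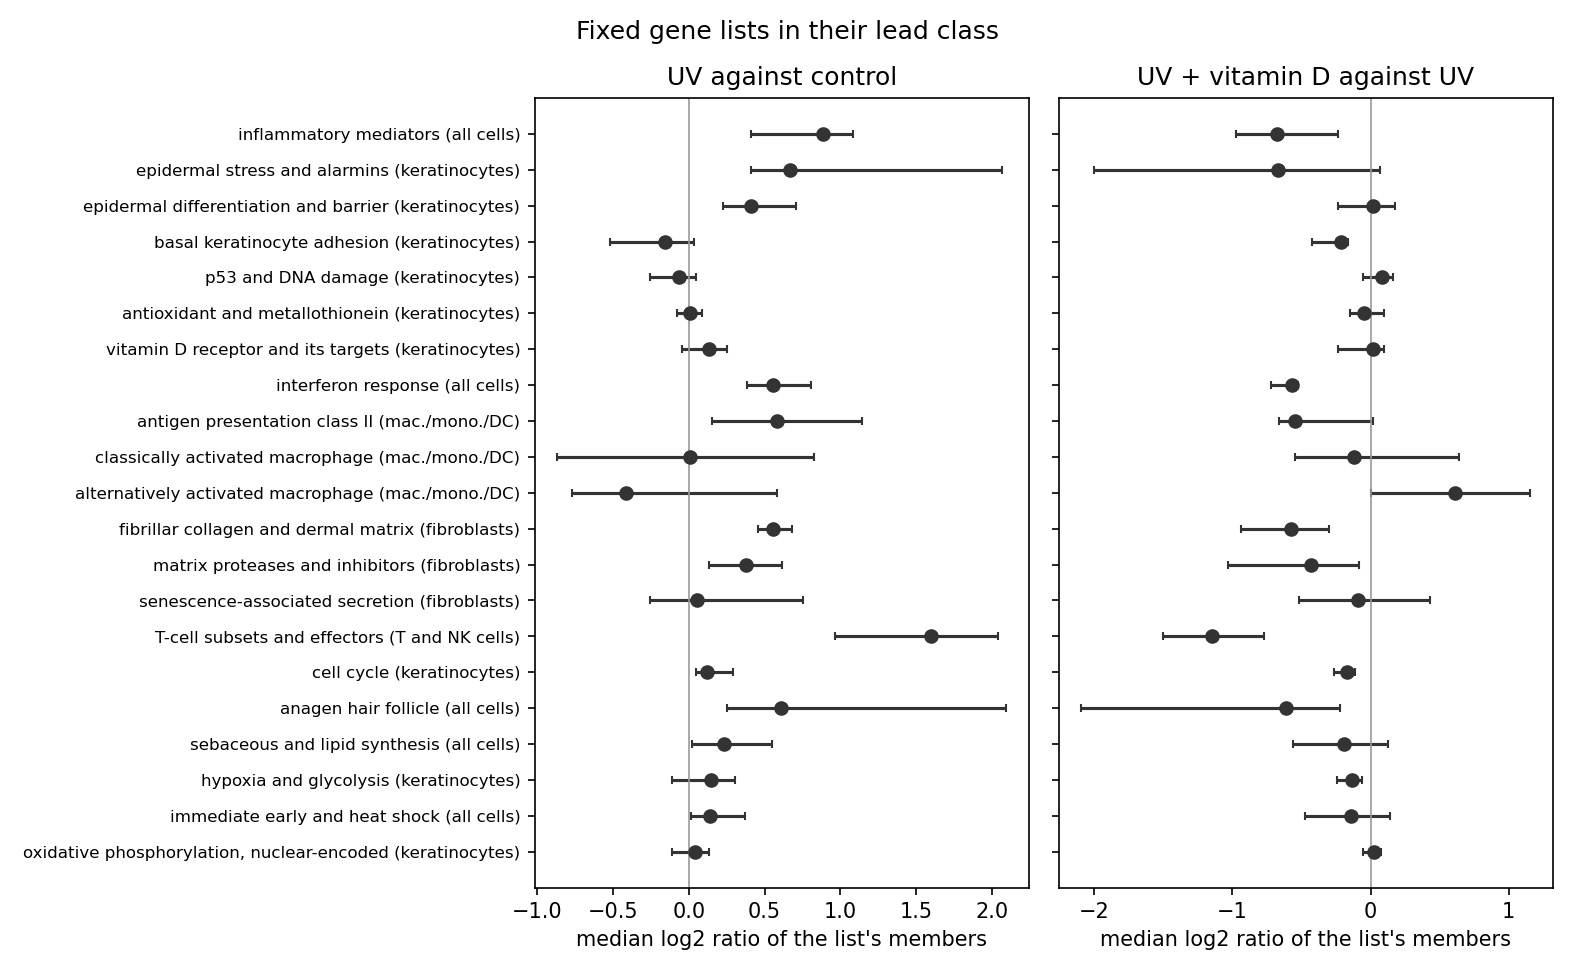
Median log2 ratio of each of 21 gene lists in its lead class (points), UV against control on the left and UV plus vitamin D against UV on the right, with 95% intervals over the list's members as bars. The T-cell list has the highest median on the left (1.59) and the lowest on the right (-1.15).

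The UV plus vitamin D against UV comparison asks how irradiated skin differed with vitamin D in place of saline. The class shares lay in the opposite direction to UV against control. Keratinocytes were 93.0% [92.3, 93.6] of cells with vitamin D, 1.41-fold higher [1.38, 1.44] than in UV. Immune cells were 2.76% [2.37, 3.20], 5.33-fold lower [4.54, 6.27], macrophages, monocytes and dendritic cells 1.45%, 7.44-fold lower [5.98, 9.26], and T and NK cells 0.936%, 3.33-fold lower [2.48, 4.48]. Fibroblasts were 3.11%, 2.22-fold lower [1.88, 2.63], and sebocytes 0.532%, 4.52-fold lower [3.09, 6.60]. Hair matrix and shaft cells and melanocytes were not found among 6199 cells, which allows up to 0.0484% at 3 cells and 0.0595% by the exact interval, and the cluster without a name held 18 cells (0.290%). With each cell assigned on its own, the log2 ratio of the T and NK cell share was -2.61, against -1.74 from clusters.

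In keratinocytes, several genes of the stress and alarmin list stood lower with vitamin D than in UV. Of 22 stress and alarmin genes, 12 were at least 1.5-fold lower and 1 higher (14 and 1 by CPM without the pseudocount), with a median of -0.67 [-2.0, 0.07] (percentile 0). Krt6b was 37.1-fold lower [32.7, 42.1], at 145 and 3.91 CPM, Krt6a 12.6-fold [11.9, 13.4] (log2 ratio -3.10, or -2.46 with basal, suprabasal and follicle cells weighted as in control) and Stfa3 35.5-fold [32.8, 38.6]. S100a8, an alarmin subunit, was 55.8-fold lower [42.7, 74.1], with a log2 ratio of -1.05 when each cell was assigned on its own, against -2.40. The differentiation list had a median of 0.01 [-0.24, 0.18], with 2 of 34 higher and 6 lower. Krt2, a keratin of the upper epidermis, was at 11.9 and 66.0 CPM, 5.55-fold higher [5.03, 6.12], Rptn 65.5-fold lower [54.2, 79.98] and Flg 4.71-fold lower [4.61, 4.81]. Lce1m, a late cornified envelope gene, was 2.05-fold higher [2.03, 2.07], and the secretory genes Scgb1a1 and Wfdc18 were 2.85-fold [2.71, 3.01] and 3.55-fold [3.13, 4.04] higher. Igkc and Ighm again met the rule, from the same UV counts of 1 cell.

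The vitamin D receptor and target list had a median of 0.02 [-0.24, 0.10] (percentile 62.4), with 1 of 21 members at least 1.5-fold higher and 4 lower (3 and 7 by CPM without the pseudocount). Vdr was at 47.8 CPM in UV and 50.3 with vitamin D, a ratio of 1.05 [0.993, 1.11], so a difference was not detectable at this depth. Cyp24a1, which vitamin D signalling is known to induce, had 5 counts in UV and 0 with vitamin D, too few for a fold. Igfbp3 was 2.38-fold higher [2.30, 2.47] and Klk6, a kallikrein protease gene, 4.58-fold lower [4.32, 4.85]. Cdkn1a was at 2408 CPM, 1.46-fold higher [1.45, 1.48], within a p53 list whose median was 0.08 [-0.05, 0.16], with 0 of 27 members past 1.5-fold either way, or 3 lower by CPM without the pseudocount. Basal adhesion genes had a median of -0.22 [-0.42, -0.16], with 2 of 17 lower and 0 higher (6 and 0 by CPM without the pseudocount), or -0.05 with basal, suprabasal and follicle cells weighted as in control; Krt14, a basal keratin, was 2.0-fold lower [1.98, 2.03]. The cell cycle list had a median of -0.17 [-0.27, -0.11], with 1 of 34 lower, or 20 by CPM without the pseudocount. The medians were -0.13 [-0.24, -0.06] for hypoxia and glycolysis, -0.04 [-0.15, 0.10] for antioxidant genes and 0.02 [-0.05, 0.08] for oxidative phosphorylation. Cluster 8 held the most keratinocytes in UV (749 cells) and cluster 2 with vitamin D (857 cells).

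In fibroblasts, matrix genes stood lower with vitamin D than in UV. Of 43 collagen and matrix genes, 21 were at least 1.5-fold lower and 0 higher, with a median of -0.58 [-0.94, -0.30] (percentile 0). Col1a1, the main chain of type I collagen, was at 15410 and 5304 CPM, 2.91-fold lower [2.83, 2.98], and Lum was 3.57-fold lower [3.34, 3.83]. Both are among the leading genes of cluster 19, which held 194 of 377 fibroblasts in UV and 46 of 193 with vitamin D. The matrix ratios may therefore also reflect the mix of fibroblast clusters. Of 24 proteases and inhibitors, 11 were lower and 1 higher, with a median of -0.43 [-1.03, -0.08]; Ctsk, a collagen-degrading cathepsin, was 2.92-fold lower [2.70, 3.17], and its log2 ratio was -0.23 in cluster 12 against -1.53. Plat, a plasminogen activator, was 2.12-fold higher [1.97, 2.27]. The senescence-associated secretion list had a median of -0.09 [-0.52, 0.43], with 4 of 27 higher and 7 lower. Hmox1 was 8.77-fold higher [8.20, 9.39] and Sult1e1 9.04-fold higher [6.56, 12.7], with a log2 ratio of 1.93 in cluster 12 against 2.64.

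Serpina3n, a serine protease inhibitor gene, was 10.8-fold lower [7.92, 15.2] in these fibroblasts and Hpgd, which degrades prostaglandins, 11.8-fold lower [5.27, 32.6]. Fam180a was 15.7-fold lower [5.99, 58.5] and Wfdc12 at least 18.2-fold lower, but in cluster 12 alone both had a log2 ratio of -0.12. Cluster 19 held most fibroblasts in UV (194 of 377) and cluster 12 most with vitamin D (147 of 193). Some named values rested on few cells: 96.9% of the Gzmc counts with vitamin D and 84.2% of the Saa3 counts in UV came from 1 cell, and both had a log2 ratio of 0.00 in cluster 12. Wfdc21 and Crct1 were 7.67-fold [6.76, 8.71] and 6.31-fold [5.56, 7.18] higher, with 36.5% and 41.4% of counts from 1 cell, and without the cells of highest doublet score their log2 ratios were 1.14 and 1.08, against 2.84 and 2.57. In keratinocytes Wfdc21 stood at 1593 and 2368 CPM and Crct1 at 2387 and 3570, and Krt5 in fibroblasts was at 83.4 and 234 CPM.

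In macrophages, monocytes and dendritic cells, named genes again stood apart in both directions. Ifnb1 was 10.1-fold higher [7.24, 14.3] with vitamin D than in UV, at 18.3 and 185 CPM, Ifit1 5.30-fold higher [4.57, 6.15] and the gelatinase gene Mmp9 7.61-fold higher [5.26, 11.1]. Ly6c2 had 1965 counts in UV and 0 with vitamin D, at least 102.987-fold lower, Ms4a4c was 66.8-fold lower [26.0, 245] and Spp1 26.7-fold lower [10.4, 98.4]. Ccr7, a receptor of migrating dendritic cells, was 25.8-fold lower [8.77, 125]. The interferon response list had a median of -0.22 [-0.56, 0.19] in this class, with 13 of 40 higher and 13 lower. Cluster 11 held most of the class in UV (459 of 589 cells) and cluster 16 most with vitamin D (75 of 90). In cluster 16 alone the log2 ratios were 1.94 for Ifnb1 against 2.79, 1.41 for Ifit1 against 2.32, 1.35 for Mmp9 against 2.38, -0.85 for Ly6c2 against -5.95, -1.77 for Ms4a4c against -4.91, -0.45 for Spp1 against -3.63 and 0.00 for Ccr7 against -3.35. Cma1, a mast cell protease gene, also met the rule, but 98.7% of its UV counts came from 1 cell.

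Alternative activation genes stood higher with vitamin D in this class, with 12 of 23 at least 1.5-fold higher, 4 lower and a median of 0.61 [0.00, 1.16] (percentile 100). Lyve1, a hyaluronan receptor, was 4.23-fold higher [3.60, 4.98] and the eotaxin gene Ccl24 3.68-fold higher [3.29, 4.11], while Gpnmb was 32.3-fold lower [8.89, 268]. In cluster 16 alone the median was -0.14, and the log2 ratios were 0.53 for Lyve1 against 1.99, 0.54 for Ccl24 against 1.84 and 0.15 for Gpnmb against -3.30. Class II antigen presentation had a median of -0.55 [-0.67, 0.02], with 1 of 15 higher and 5 lower, and 0.52 in cluster 16 alone. The classically activated list had a median of -0.12 [-0.55, 0.64], or 0.57 in cluster 16 alone, with 4 of 15 higher and 3 lower; Il1b was 3.77-fold lower [3.25, 4.41], with a log2 ratio of -0.63 in cluster 16 against -1.89. In T and NK cells, 21 of 27 T-cell genes were lower and 4 higher, with a median of -1.15 [-1.51, -0.77], or -0.45 with each cell assigned on its own. Gzma, a granzyme gene, had 136 counts in UV and 0 with vitamin D, at least 24.26-fold lower, and Pdcd1, an inhibitory receptor of activated T cells, was 8.33-fold lower [3.91, 21.2], with a log2 ratio of -1.57 with each cell assigned on its own against -2.37.

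Summed over all cells, 22 of 40 inflammatory mediators were at least 1.5-fold lower with vitamin D than in UV and 0 higher (26 and 1 by CPM without the pseudocount), with a median of -0.68 [-0.97, -0.23] (percentile 0). Csf3, a growth factor for neutrophils, was 23.6-fold lower [19.5, 28.9], Vcam1 14.1-fold [12.4, 16] and Ccl8 7.0-fold [6.71, 7.31]. With classes weighted to control shares the median was 0.01. Of 40 interferon response genes, 19 were lower and 0 higher (36 and 1 by CPM without the pseudocount), with a median of -0.57 [-0.72, -0.53], or -0.18 with classes weighted and -1.51 with a pseudocount of 1 CPM; Ifi27l2a, an interferon-induced gene, was 9.20-fold lower [8.70, 9.73]. The median of the hair follicle growth list was -0.61 [-2.10, -0.22], with 12 of 23 lower and 1 higher (18 and 1 by CPM without the pseudocount), or -0.05 with classes weighted and -2.57 with a pseudocount of 1 CPM. The weighting leaves out hair matrix and shaft cells, which control lacked. The medians were -0.19 [-0.56, 0.13] for sebaceous and lipid genes, with 7 of 25 lower (12 by CPM without the pseudocount), and -0.14 [-0.48, 0.14] for immediate early and heat shock genes, with 9 of 36 lower and 2 higher, or 0.14 with classes weighted; Fos, an immediate early transcription factor, was 3.20-fold lower [3.12, 3.29].

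**Figure D3:**
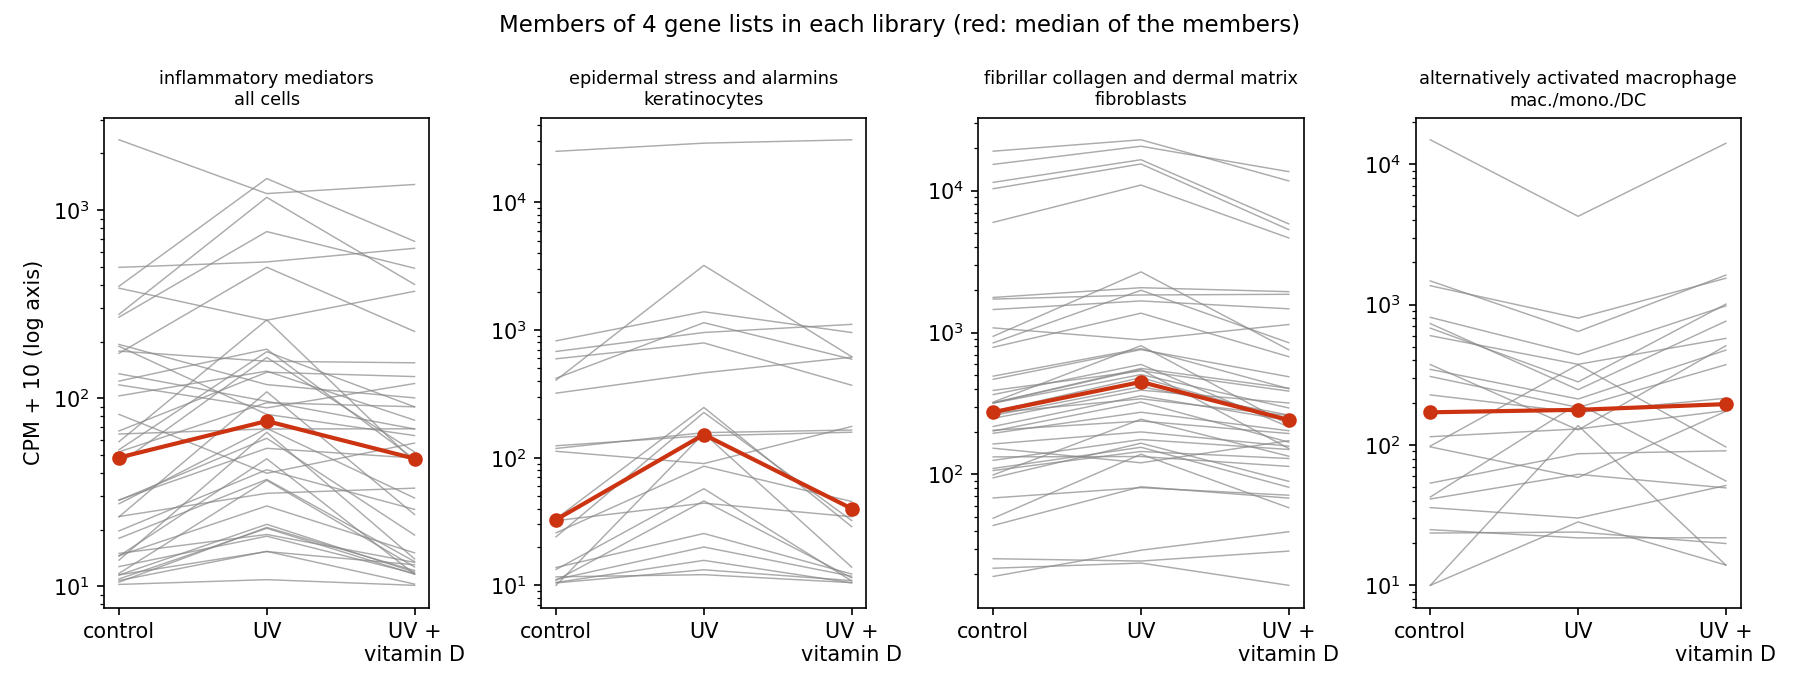
CPM plus 10 (log axis) of the members of 4 gene lists in the 3 libraries, with 1 grey line per gene and the median over members in red. In keratinocytes the stress gene Krt6a goes from 23.3 CPM in control to 237 in UV and 18.9 with vitamin D.

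UV plus vitamin D against control compares irradiated, treated skin with unirradiated skin. The shares of keratinocytes (ratio 0.996 [0.987, 1.005]) and of macrophages, monocytes and dendritic cells (0.984 [0.754, 1.28]) showed no difference detectable at this depth. Basal keratinocytes were 1.59-fold fewer [1.46, 1.72] as a share of cells, and fibroblasts 1.41-fold more [1.16, 1.72]. Hair follicle keratinocytes were 1.66-fold fewer [1.43, 1.93], T and NK cells 1.52-fold fewer [1.12, 2.07] and immune cells 1.28-fold fewer [1.07, 1.54]. The differentiation list was higher than in control, with 12 of 34 genes at least 1.5-fold higher and a median of 0.36 [0.16, 0.63] (percentile 100), and basal adhesion was lower, with 5 of 17 lower (10 by CPM without the pseudocount) and a median of -0.42 [-0.72, -0.36] (percentile 0). With basal, suprabasal and follicle cells weighted as in control, these medians were 0.29 and -0.02. The medians against control were 0.05 [-0.12, 0.18] for inflammatory mediators, 0.03 [-0.01, 0.07] for interferon response and -0.03 [-0.19, 0.06] for fibroblast matrix genes. Of 40 mediators, 6 were higher and 6 lower (12 and 12 by CPM without the pseudocount). Of 39 interferon genes, 0 were higher and 1 lower (12 and 8 by CPM without it), and of 42 matrix genes, 2 and 5. Other lists also held members apart from control. Of 25 senescence-associated secretion genes, 9 were higher and 1 lower. Of 22 stress and alarmin genes these were 5 and 1 (10 and 4 by CPM without it), and of 22 T-cell genes, 9 and 6. Nr1d1 in keratinocytes was at 50.1 CPM in control and 17.1 with vitamin D, near the 16.7 of UV.

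Across genes, the UV plus vitamin D against UV ratios ran opposite to the UV against control ratios. With the UV cells split at random into separate sets for the 2 ratios, Pearson r was -0.62 in keratinocytes (Spearman rho -0.46, 12485 genes), -0.51 in fibroblasts (rho -0.45, 6112 genes) and -0.58 in macrophages, monocytes and dendritic cells (rho -0.52, 6123 genes), as means over 20 splits. Genes are not independent replicates, so no p is given for these 3 relations. Simulated libraries with no difference gave r of 0.00 in keratinocytes; the split and the simulations cover counting error only. A deviation of the single UV library enters the 2 ratios with opposite sign, so it gives a negative relation across genes by itself, and ratios below 0 among genes chosen as higher in UV. The covariance was -0.0421 in keratinocytes against 5.6e-06 simulated, -0.147 in fibroblasts against 0.000160, and -0.222 in macrophages, monocytes and dendritic cells against -0.000132. Of 130 keratinocyte genes at least 2-fold higher in UV in 1 part of the cells, 113 (86.9%) had a UV plus vitamin D against UV ratio below 0 in the other part, and their median against control was 1.22 in UV and 0.43 [0.20, 0.59] with vitamin D. The 12 genes at least 2-fold lower had medians of -1.16 in UV and -1.05 [-1.23, -0.81] with vitamin D. In fibroblasts, 76 such lower genes went from -0.99 to -0.20 [-0.41, -0.01] and 243 higher genes from 0.67 to 0.18 [0.13, 0.26]. In macrophages, monocytes and dendritic cells, 168 lower genes went from -0.73 to 0.00 [-0.07, 0.07] and 671 higher genes from 0.81 to 0.16 [0.10, 0.22]. In each class, both medians are set against the single control library, so a deviation of that library moves them the same way.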

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

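The alternatives that leave out cells of high doublet score or with markers of an unrelated lineage, drop the rRNA gene from totals, weight keratinocyte classes as in control take single clusters or count list members by CPM without the pseudocount were chosen after seeing the data, as were all alternatives for single genes. No paired analysis was possible because each group has 1 library. Shares of cells with a count are not reported, so cells were not thinned. Of 631 alternative values of 42 list medians, 606 kept their sign and 25 did not; 18 moved out of the interval, and 4 turned against a median whose interval lay away from 0. Of 80 values of 10 share ratios, 80 kept their direction and 11 moved. Of 2404 values of 221 named gene ratios, 1884 stayed within the interval, 514 moved out of it and 6 reversed; 14 in all had the other sign. Counts of list members by CPM without the pseudocount, in which low genes are not shrunk, differed by over 1.5 times for several lists, among them cell cycle, at 20 against 3 higher (UV against control) and 20 against 1 lower (UV plus vitamin D against UV), interferon response, at 32 against 18 higher and 36 against 19 lower, hair follicle growth, at 19 against 12 higher, sebaceous genes, at 13 against 7 higher and 12 against 7 lower, vitamin D targets, at 8 against 4 higher and 7 against 4 lower, p53 genes, at 6 against 3 lower in UV, and basal adhesion, at 6 against 2 lower with vitamin D. The causes were not tested except where the alternative's construction gives them. Library depth of the smaller classes limits single genes: macrophages, monocytes and dendritic cells had 736720 counts in control and 507076 with vitamin D.

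With each cell assigned on its own, the log2 share ratios (UV against control, then UV plus vitamin D against UV) were 2.67 and -2.72 for immune cells, -0.44 and 0.43 for keratinocytes, 1.92 and -1.44 for fibroblasts, and 2.50 and -2.61 for T and NK cells, and the T-cell list median, UV plus vitamin D against UV, was -0.45. Without cells of high doublet score the keratinocyte ratios were -0.46 and 0.45, and at Leiden resolution 2 the fibroblast ratio was 1.91. With a pseudocount of 1 CPM, which shrinks low genes less, the medians were 1.38 and -1.08 for inflammatory mediators, 1.54 and -1.51 for interferon response, 0.54 and -0.61 for cell cycle, -2.57 for hair follicle growth and -0.27 for hypoxia (UV plus vitamin D against UV), and 0.58 for sebaceous genes (UV against control). With classes weighted to control shares, which takes out shifts in class shares, they were -0.0102 and 0.00861 for inflammatory mediators, 0.21 and -0.18 for interferon response, 0.0474 and -0.0474 for hair follicle growth, and 0.0088 for immediate early genes (UV against control). For hair follicle growth this weighting leaves out the hair matrix and shaft cells, which control lacked. With each cell weighted the same, interferon response was -0.72 with vitamin D against UV, and with keratinocyte classes weighted as in control, basal adhesion was -0.0498. In cluster 16 alone, class II antigen presentation was -0.28 and 0.52, and alternative activation with vitamin D against UV was -0.14.

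The relation across genes had r of -0.72, -0.67 and -0.69 in keratinocytes, fibroblasts, and macrophages with monocytes and dendritic cells when all UV cells entered both ratios, where the shared library alone gave -0.65, -0.31 and -0.16. With genes of at least 200 counts it was -0.62 in fibroblasts and -0.69 in macrophages, monocytes and dendritic cells. Single genes that reversed were Ereg in fibroblast cluster 19 (0.20), Slpi in fibroblasts with cells assigned on their own (1.5), without cells of high doublet score (1.23) and in cluster 19 (0.44), H2-DMb1 in cluster 16 (-0.42), all UV against control, and Gpnmb in cluster 16 (0.15), with vitamin D against UV.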

Other observations

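The tests of a loss of keratinocytes, of counting error in the shared UV cells, of a mixture of cells, of the time of day and of the weighted clock genes other than Nr1d1 were chosen only after the result was seen; the tests of hair growth and of the basal keratinocyte share on Nr1d1 were set before their results were seen. Clock genes, chosen after their values were seen, separated control from both irradiated libraries in keratinocytes. Apart from Bhlhe41, which had too few counts, all 8 genes taken to peak with Nr1d1 were below 0 in UV and in UV plus vitamin D against control, with median log2 ratios of -0.43 and -0.49. Among them Dbp, with 29, 6 and 21 counts in control, UV and UV plus vitamin D, hardly differed, at -0.03 and -0.01. Bhlhe41 was at 0.01 and -0.01. Tef, a clock output gene, was at 14.3, 3.15 and 3.76 CPM in control, UV and UV plus vitamin D, and Ciart, a clock repressor, at 7.22, 0.625 and 1.57 CPM. Arntl, an activator of the clock that peaks against Nr1d1, was 0.34 and 0.50 higher on the log2 scale. In fibroblasts Arntl was 1.17 and 1.01 higher and Nr1d1 was -1.68 and -2.03. In the UV library, hair matrix and shaft cells held 160 CPM of Mki67, a marker of dividing cells, against 6.24 in hair follicle keratinocytes, and 36.3 CPM of Lef1, a transcription factor of the hair shaft lineage, against 0.749.

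The UV library held larger shares of nearly all classes other than interfollicular keratinocytes. A loss of keratinocytes from the cell suspension would raise the other classes alike, and is argued against as the whole cause: with the 5.12-fold rise of all cells outside the keratinocytes, control would need 102 hair matrix and shaft cells, and 0 were found. Cluster 11, named dendritic cells and with 459 of its 494 cells from UV, had a share 38.2-fold higher [24.5, 59.7]. Cluster 16, named macrophages and monocytes, had a share 1.90-fold higher [1.48, 2.44]. By mean relative marker expression, cluster 11 scored higher for macrophages and monocytes (0.41) than for dendritic cells (0.28), so these ratios do not separate the cell types. For fibroblasts, sebocytes, T and NK cells, and macrophages with monocytes and dendritic cells a loss stays open: the highest lower bound was 2.21 times the lowest upper bound, or 1.35 without sebocytes and with each cell assigned on its own, and these bounds cover counting error only. For the hair matrix and shaft cells, a candidate explanation is that the UV skin piece held follicles in the growth phase, whether from irradiation, the animal or the site of sampling. The cell cycle list had a median log2 ratio of 2.02 [1.69, 2.31] in these cells against hair follicle keratinocytes, with 34 of 35 genes at least 1.5-fold higher, but Tubb5 of that list is among the genes that define the cluster, so the value restates what the cluster is and leaves the explanation open.

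The vitamin D library lay opposite to UV across genes and close to control in many. Counting error of the shared UV cells alone is argued against, since the covariance in keratinocytes with separate UV cells was -0.0421 and the simulated one 5.6e-06; a deviation of the single UV library enters both ratios with opposite sign and is not covered by that test. A vitamin D library that mixes cells of the control and UV samples themselves is argued against as well: a mixture with 25.9% UV keratinocytes would need 130 hair matrix and shaft cells, and 0 were found. These cells may be a trait of the UV skin piece. Their absence therefore cannot decide on a mix of affected and unaffected cells within the vitamin D skin. An effect of vitamin D, a weaker irradiation of that animal and a UV library that stands apart for reasons of its own may each give this pattern, and stay open.

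For the clock genes, fewer basal keratinocytes in both irradiated libraries are argued against: with basal, suprabasal and follicle cells weighted as in control, the log2 ratio of Nr1d1, UV against control, was -1.16, against -1.17 unweighted. Weighted in this way, the medians of the 8 genes that peak with it were -0.42 in UV and -0.48 in UV plus vitamin D, against -0.43 and -0.49. A different time of day at collection of the control skin may also give the pattern, and cannot be told apart from an effect of irradiation. The median of the 5 genes that peak against Nr1d1 was 0.0331 in UV and 0.0846 in UV plus vitamin D against control. Clock and Cry1 were below 0 in UV, and at a bound of 0.1 these medians do not decide the question. The bound for this test was changed from 0 to 0.1 after the value was seen. At the bound of 0, these medians and those of the 8 genes go with a different time of day. In fibroblasts the medians were 0.44 and 0.33 for 4 genes that peak against Nr1d1, with 1 of them below 0 in UV. Those of 2 genes that peak with Nr1d1 were -1.26 and -1.18. The fibroblast medians also go with a different time of day, but rest on few genes. The effect of UV on clock genes stays open as untested.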
